A study of Mus musculus with 8 samples.

How the data were processed

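The libraries were made by the submitters from mRNA of whole embryos, and their processing notes name RSEM for expression estimates on genome build mm9. The RSEM version and any later tool are not given in the sources used here. The Meis1 values are deposited by the authors as a signal, namely counts divided by library size factors and averaged over the libraries of each group, under column names that match the result table of the DESeq package. The log2 values deposited by the authors are ratios of those group means, and the p-value and adjusted p-value columns are those of the authors' test. Per the file headers, a ratio of residual variance to fitted variance is given for each group. The Prep1 values are expected counts as deposited, whole numbers with a count of 0 written as 0.1, and the deposited log2 ratio of them is not scaled for library size. Both tables were filtered by the authors by a criterion that is not given, and the lowest sum of the 2 counts in the Prep1 table is 5.

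There were 18941 entries for 18904 genes in the Meis1 table, and 17382 entries for 17348 genes in the Prep1 table, since 37 and 34 entries repeat a gene. The main test was planned for counts per library, and the Meis1 table held group means instead, so the unit differed from the one the plan assumed. Each mean is a sum of 3 whole counts, each divided by its library's size factor, and the printed precision leaves 1 possible set of whole counts for 18885 (WT) and 18890 (KO) of the 18904 genes. Where several sets were possible, the deposited variance ratio settled 11 of 19 genes in WT and 7 of 14 in KO. In 3000 simulated genes, 100% had 1 answer and 100% of these were right. Their size factors were in no simple ratio to each other, which this recovery needs. With wrong step sizes 0% of the real genes tried had an answer, and only genes of low to moderate mean were tried. Neither check reached the highest means, where the genes left out below lie. The fitted variance implied by the recovered counts followed the mean with a Spearman correlation of 0.9995 in both groups, against 0.8181 and 0.826 with the variance ratios shuffled. The 10 genes not settled in both groups (mt-Nd5, mt-Cytb, mt-Co1, mt-Nd1, Srsf2, H19, Hbb-y, Eef1a1, Hbb-bh1 and Hba-x) were left out. Their log2 differences in the authors' deposited table lie between -0.57 and 0.52, with an adjusted p of 1 each. The recovered libraries cannot be tied to the sample codes of the labels. Replicate values in a group were not copies, since chi-square per gene within groups was between 6.83 and 18.8. Between groups it was between 3.19 and 18.2, and 3 pairs (WT a and KO c at 3.19, WT c and KO c at 4.45, WT b and KO b at 4.92) were more alike than any pair within a group.

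The Meis1 comparison used edgeR's quasi-likelihood test on the recovered counts with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment, with DESeq2 and limma-voom beside it. The 29 gene lists were fixed before the data were examined, as were the tests, the thresholds and the rule for named genes. Of these, 26 lists with at least 3 measured members were tested with camera of limma at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. The lens and trophoblast lists had too few measured members, and the sex-linked list is described per library. Pf4 and Lyve1 each belong to 2 lists, as do a few other members, so the lists are not independent.

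The Prep1 comparison has 1 library per group and no test. Its log2 ratios are of TMM-scaled CPM with a prior count of 2, over genes with at least 20 counts in the higher library. The 95% exact intervals cover counting error only. The median of each list was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. In simulated counts 99% of genes changed by 1.5 log2 units and 0.29% of unchanged genes passed 2-fold. These counts held counting noise only, and changes were placed in genes with a mean of at least 50 counts. Between real Meis1 WT libraries 2.99% to 6.64% of genes passed the same rule, so 0.29% is no error rate for 2 real libraries. Of 200 simulated lists without a shift, 3% fell outside the central 95%, and a list shifted by 0.4 had a percentile of 99.9.

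Named genes followed a fixed rule. For Meis1 these are the TALE genes, the 12 genes with the smallest p in each direction (used because fewer than 10 genes passed FDR 0.05), and the 2 members with the smallest p of each list. For Prep1 these are the TALE genes, the 12 highest and 12 lowest ratios among genes with at least 50 counts in the higher library, and up to 4 members of each list with the largest ratio in size, from which the text takes examples. Genes called in the authors' deposited table, and Bnip3, Aldoa, Hoxc4, Hoxa2, Rab27b, Plek, Vwf, Csf1r, Slc4a1, Alas2, Lin28a, Igdcc3 and Hmga1 in the Meis1 libraries, were chosen after their values were seen. A few genes that the rule names are not reported here. Gene coordinates are on mm9 as deposited.

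The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.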

Results

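Messenger RNA of whole C57BL/6 mouse embryos at embryonic day 11.5 was sequenced in 8 libraries. In the first comparison, 3 libraries labelled Meis1 knockout (KO) were set against 3 of wild-type (WT) littermates. In the second, 1 library labelled hypomorphic for Prep1, the gene listed as Pknox1, was set against 1 of WT littermates. Whether a library holds 1 embryo or several is not given in the sources used here. Meis1 and Prep1 belong to the TALE homeobox family of transcription factors, and the series asks what the loss of each does to transcription. The deposited Meis1 table gives group means only, so the whole counts behind those means were worked back for each library, and the 6 libraries are called a, b and c within their group by size. Their totals were 4316594, 4562066 and 6263123 counts for WT a, b and c, and 4291920, 4758709 and 4852417 counts for KO a, b and c. The Prep1 libraries held 4000984 counts (WT) and 5893401 counts (hypomorph).

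The first comparison asks which transcripts differ in embryos labelled Meis1 KO. Ppbp, a platelet chemokine, was nearly absent from the KO libraries, and Pf4, another platelet chemokine, was below the WT mean in each, though KO library a was level with 1 WT library. Anterior Hox genes such as Hoxa3, Hoxd4 and Hoxd3, which pattern the hindbrain and neck, had higher means in the KO group. Transcripts induced by low oxygen, among them Vegfa, Bnip3 and the glycolytic enzyme gene Aldoa, stood far above the other libraries in KO library a alone. Meis1 itself was lower in the KO libraries but was not lost from them.

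Meis1 (chromosome 11, 18780433 to 18918961 in mm9) read 97.2 ± 12.7 CPM (counts scaled to library depth; SD, n = 3) in WT and 74.6 ± 9.81 CPM (SD, n = 3) in KO, a log2 difference of -0.38 with a standard error (SE) of 0.16. Its KO values were 85.8, 67.7 and 70.3 CPM in libraries a, b and c, all below its WT values of 92.1, 87.9 and 112 CPM. The part of the gene that the KO allele lacks is not given in the sources used here, so counts over the whole gene leave the labels unchecked. Meis2, the closest paralogue measured, read 214 ± 15.8 CPM (SD, n = 3) in WT and 280 ± 37.1 CPM (SD, n = 3) in KO, a log2 difference of 0.39 without overlap between the groups. Pknox1 read 29.3 ± 2.08 CPM (SD, n = 3) in WT and 24.8 ± 0.66 CPM (SD, n = 3) in KO, a log2 difference of -0.24, again without overlap. Among the partners that bind DNA with these factors, the log2 difference was 0.17 for Pbx3 and 0.61 for Pbx4 (0.37 without WT b). The other TALE genes reported here lay between -0.59 (Irx6, -0.22 without WT c) and 0.28 (Irx3, 0.15 without KO a). The TALE genes reported here all had an adjusted p of 0.9999 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The signs of Meis3, Pbx2, Pknox2, Tgif1, Irx2, Irx4, Irx5 and Mkx, all near 0, depended on the libraries or settings used.

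The 12 genes with the smallest p among those higher in KO are given first. Robo3, a guidance receptor of axons that cross the midline, read 26.5 ± 5.77 CPM (SD, n = 3) in WT and 50.1 ± 11.3 CPM (SD, n = 3) in KO, a log2 difference of 0.91 (SE 0.21). Nrxn3, a synaptic adhesion gene, differed by 1.04 (SE 0.31) and Cacna1h, a calcium channel gene, by 0.50 (SE 0.15) on the log2 scale. Hoxa3 read 17.5 ± 2.9 CPM (SD, n = 3) in WT and 28.8 ± 1.06 CPM (SD, n = 3) in KO, a log2 difference of 0.72 (SE 0.18). Hoxd4 differed by 0.94 (SE 0.26) and Hoxd3 by 0.73 (SE 0.22), and only Hoxd3 among the 12 had overlapping groups. Pde4b, a phosphodiesterase gene, and Gm129 had log2 differences of 1.32 and 2.02, with their highest values in KO a (81.2 and 40.6 CPM), and were at 0.64 and 1.12 without it. Esr1, the oestrogen receptor gene, differed by 1.86 at means of 0.67 and 2.47 CPM. The predicted genes Gm23935, Gm11149 and Gm16172 differed by 1.27, 1.05 and 0.85, and reads of such genes can be shared with near-identical copies.

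Ppbp had the smallest p among the 12 genes named as lower in KO. It (chromosome 5, 91197544 to 91199086) had 16, 43 and 73 counts in WT a, b and c and 0, 2 and 1 counts in KO a, b and c. Summed over libraries, this is 132 against 3 counts, a log2 ratio of -5.32 with a counting interval of -7.62 to -3.74. Pf4, its neighbour (91201461 to 91202407), read 11.2 ± 5.44 CPM (SD, n = 3) in WT and 2.8 ± 2.02 CPM (SD, n = 3) in KO, a log2 difference of -2.04 (SE 0.53), with KO a (5.08 CPM) level with WT a (4.94 CPM). Lmo2, a regulator of early blood formation, read 94.8 ± 4.46 CPM (SD, n = 3) in WT and 66.2 ± 5.7 CPM (SD, n = 3) in KO, a log2 difference of -0.52 (SE 0.13). Mrc1, the macrophage mannose receptor gene, differed by -0.77 (SE 0.26), and Rgs18, a signalling regulator of platelets, by -2.34 (SE 0.62). Gpr34 and Sykb, which act in myeloid and other blood cells, differed by -2.06 (-3.45 without KO a, -1.46 without KO b) and -0.70. Rabep2, Rab40b, Pcdhb18, Tmem144 and Pih1d2 differed by -0.63, -1.65, -1.78, -1.54 and -1.19. The WT means of Rgs18, Gpr34, Rab40b, Pcdhb18, Tmem144 and Pih1d2 were 2.53 to 4.18 CPM, with at most 26 counts in any library. Without 1 library, Rgs18 lay between -2.97 and -1.745, Rab40b between -2.017 and -1.234 and Pcdhb18 between -2.068 and -1.387. Tmem144 lay between -1.918 and -1.107 and Pih1d2 between -1.627 and -0.918.

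With edgeR, 0 of 14438 genes passed a false discovery rate (FDR) of 0.05. There were 225 genes (1.56%) at an unadjusted p under 0.05, a share below the 5% set by chance, with 123 when WT c was left out and 536 when KO b was left out. DESeq2 called 1 gene, Ppbp (log2 -5.25, adjusted p = 0.00133, against 0.385 with edgeR), limma-voom called 0 (194 at an unadjusted p under 0.05), and edgeR with 2 surrogate variables called Ppbp and Pf4 (adjusted p = 0.0321 for both). The groups did not overlap in 817 genes (5.66%), where chance gives 10%, with 408 higher and 409 lower in KO. Counts were also simulated at this depth, with the spread typical of each gene's mean. There the edgeR test called 75% of 2-fold and 96% of 4-fold changes, with 7 false calls among 14267 genes. Changes were placed only in genes with an average log2 CPM above 2, and no simulated library stood apart as KO a does. Gm129, with a real log2 difference of 2.02 without overlap, had an adjusted p of 0.9999 with edgeR. These rates can therefore be too high for the real libraries, and 0 calls do not exclude such changes. The libraries did not part by genotype along the first principal component (40.6% of the variance), where WT a, b and c stood at -13.9, 29.7 and 0.5 and KO a, b and c at -33.7, 25.4 and -8.

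**Figure D1:**
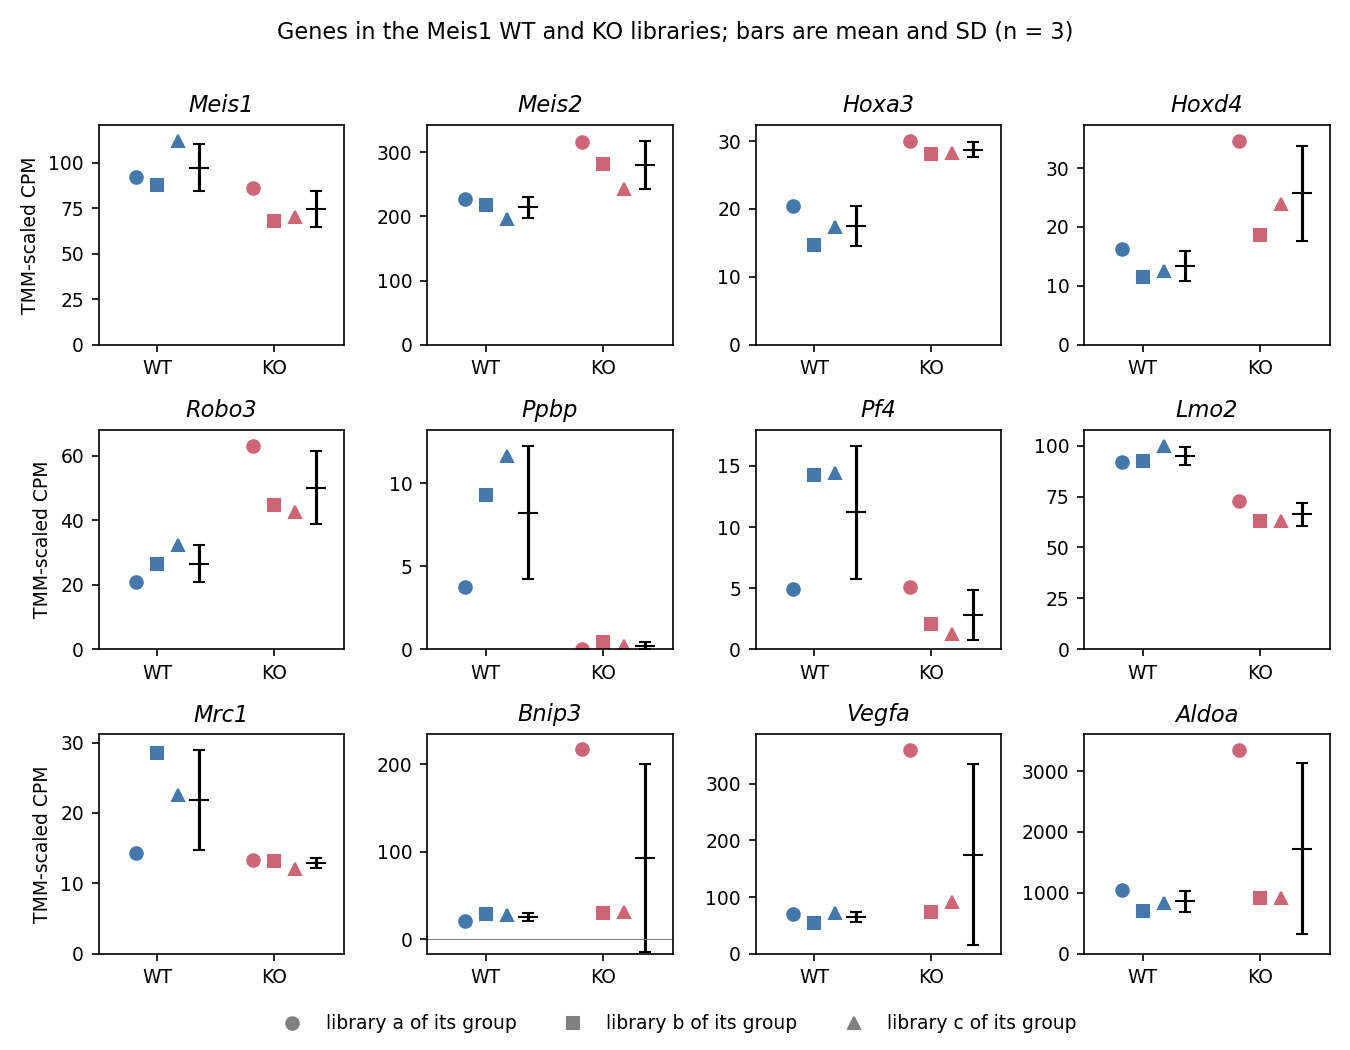
TMM-scaled CPM of 12 genes in each WT (blue) and KO (red) library, with the mean and SD of each group in black (n = 3). Ppbp is between 3.77 and 11.6 CPM in WT and at most 0.42 CPM in KO, while Bnip3, Vegfa and Aldoa are high in KO a alone.

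Of 26 fixed gene lists tested with camera at a preset correlation of 0.01, 14 passed FDR 0.05, with 9 higher and 5 lower in KO. With an estimated correlation 0 lists passed (lowest adjusted p = 0.291), and fry passed 0 (lowest adjusted p = 0.684), so the lists below describe these 6 libraries. Leaving out 1 library gave between 7 (without WT c) and 15 (without WT b) lists. Hox genes of paralogue groups 1 to 4 rose by the preset test, with 11 of 11 members above 0 and a median log2 difference of 0.37 (limma camera adjusted p = 2.71e-11, and adjusted p = 0.291 with an estimated correlation). The call held without any 1 library, with the median at 0.29 without WT c and 0.59 without WT a. Against the WT mean, the list's median was 0.266, -0.212 and -0.137 in WT a, b and c. It was 0.498, 0.248 and 0.503 in KO a, b and c, so WT a lay above KO b. Hoxa3, Hoxd4 and Hoxd3 passed when adjusted over the list alone, and 0 members passed over all genes. By their mm9 coordinates, Hoxd4 lies within the Hoxd3 entry and Hoxa5 within the Hoxa3 entry. Reads may be shared there, so these members need not be independent. Hoxc4 differed by 0.37 and Hoxa2 by 0.40, both without overlap between groups. Hox genes of groups 5 to 8 had 11 of 11 members above 0 and a median of 0.29 (limma camera adjusted p = 2.84e-05, and adjusted p = 0.417 with an estimated correlation). Hoxa5 (0.49) and Hoxb7 (0.51, and 0.29 without WT c) had the smallest p, while Hoxb5 differed more, by 0.64. The call for this list was lost in limma camera without WT c (median 0.09, adjusted p = 0.095) or KO b (median 0.28, adjusted p = 0.113). Its median was 0.60 without WT b. Hox genes of groups 9 to 13 had a median of -0.03. Hoxd12 was at -0.75 (-1.16 without KO b, -0.51 without KO a) and Hoxc9 at 0.47 (0.30 without KO b).

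Megakaryocyte and platelet genes fell by the preset test, with 12 of 15 members below 0 and a median log2 difference of -0.46 (adjusted p = 4.54e-10, and adjusted p = 0.291 with an estimated correlation). Ppbp and Pf4 passed when adjusted over the list alone. Rab27b and Plek, which serve granule release, differed by -0.93 and -0.92, whereas Vwf, also made by endothelium, differed by 0.16. The median per library was -1.13 in KO b, -0.30 in KO c and 0.02 in KO a, and without KO b the list's median was -0.17 (limma camera adjusted p = 0.00085), against -0.83 without KO a. Macrophage genes had 17 of 21 members below 0 and a median of -0.39 (limma camera adjusted p = 1.59e-06, and adjusted p = 0.417 with an estimated correlation). Against the WT mean, the macrophage median was -0.57 in WT a, 0.371 in WT b and 0.047 in WT c. In KO a, b and c it was -0.177, -0.307 and -0.384, so WT a lay below every KO library. Csf1r, the receptor for macrophage growth factor, differed by -0.60 and Lyve1 by -1.18, and the call was lost in limma camera without WT b (median -0.06, adjusted p = 0.0797). Erythroid genes other than globins, among them Nfe2 (0.58, and 0.27 without KO a), Spna1 (0.44, and 0.23 without WT b), Slc4a1 (0.47) and Alas2 (0.42), went the other way, with 29 of 32 members above 0 and a median of 0.29 (adjusted p = 7.36e-07, and adjusted p = 0.441 with an estimated correlation). Without KO a their median was -0.015 (limma camera adjusted p = 0.985), without WT b it was 0.18 (adjusted p = 0.0797), and without KO b it was 0.54. Of the adult-type alpha globins, near-identical copies whose reads can be shared, Hba-a2 differed by 0.65 and Hba-a1 by 0.24 (-0.04 without KO a). The adult beta globins Hbb-b1 and Hbb-b2 went the other way, by -0.82 and -0.16. The globin list was tested on 5 members, without Hbb-y, Hbb-bh1 and Hba-x, whose counts were not settled. In the authors' deposited table their log2 differences are 0.119, 0.479 and 0.516.

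Hepatoblast and yolk sac endoderm genes had 16 of 18 members below 0 and a median log2 difference of -0.74 (adjusted p = 1.96e-08, and adjusted p = 0.417 with an estimated correlation). Alb, the serum albumin gene, differed by -1.67 (SE 0.65) and Apoa1 by -1.29 (SE 0.54; -0.33 without WT c). Their WT values were uneven, with Alb at 7.53 CPM in WT a against 86.2 and 78.8 CPM in WT b and c, and without WT c the list's median was -0.18 (limma camera adjusted p = 0.0571), against -1.15 without WT a.

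Hypoxia-induced and glycolytic genes had 30 of 30 members above 0 and a median log2 difference of 0.87 (adjusted p = 3.86e-24, and adjusted p = 0.417 with an estimated correlation). The median against the WT mean was 1.73 in KO a, 0.09 in KO b and 0.11 in KO c, and without KO a the list's median was 0.10 (limma camera adjusted p = 0.00388). Vegfa, the vascular growth factor gene, read 359 CPM in KO a, 73.5 and 91.4 CPM in KO b and c, and 65 ± 9.16 CPM (SD, n = 3) in WT. The log2 difference was 1.42 for Vegfa and 1.42 for Egln3, an oxygen sensor gene that read 45.2 CPM in KO a and 13.8 and 11.3 CPM in KO b and c. Flt1, a receptor for Vegfa in endothelium, followed with 85.1 CPM in KO a and 26.4 and 27.4 CPM in the other KO libraries. Without KO a the log2 differences of Vegfa, Egln3 and Flt1 were 0.35, 0.53 and 0.33.

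Neuron genes, with Nhlh2 (0.50) and Nhlh1 (0.43) at the smallest p, had a median of 0.15 (limma camera adjusted p = 0.00109, and adjusted p = 0.507 with an estimated correlation). This call was lost in limma camera without WT c (median 0.02, adjusted p = 0.587) or KO b (median -0.006, adjusted p = 0.798). Immediate early and stress genes, with Egr1 (0.92, and 0.54 without KO a) and Cyr61 (0.60, and 0.18 without KO a), had a median of 0.19 (adjusted p = 0.00349, and adjusted p = 0.417 with an estimated correlation), lost without KO a (median 0.17, adjusted p = 0.106). Neural crest, glial and sympathetic genes, with Th, an enzyme gene of catecholamine synthesis, at 0.86 (0.51 without WT b), had a median of 0.21 (adjusted p = 0.00386, and adjusted p = 0.291 with an estimated correlation), lost without WT c (median 0.09, adjusted p = 0.188) or KO b (median 0.14, adjusted p = 0.13). Hedgehog pathway genes, with Gli1 (0.51) and the receptor gene Ptch1 (0.48), had a median of 0.16 (adjusted p = 0.00942, and adjusted p = 0.291 with an estimated correlation), lost without WT c (median 0.10, adjusted p = 0.0768) or KO c (median 0.12, adjusted p = 0.084). Neural progenitor genes, with Notch1 (0.45, and 0.23 without KO a) and its ligand gene Dll1 (0.42, and 0.20 without KO c), had a median of 0.11 (adjusted p = 0.0272, and adjusted p = 0.480 with an estimated correlation), lost without WT b (median 0.08, adjusted p = 0.585) or KO c (median 0.02, adjusted p = 0.903). Leaving out other libraries raised some of these medians, that of neural progenitor genes to 0.30 without WT a and 0.24 without KO a or KO b, that of neuron genes to 0.27 without KO a and that of immediate early genes to 0.28 without KO c.

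Of the limb and craniofacial mesenchyme genes, Msx1 differed by -0.30 and Dlx5 by -0.58 (-0.89 without KO b, -0.36 without KO c). The list had a median of -0.11 (limma camera adjusted p = 0.0144, and adjusted p = 0.441 with an estimated correlation). In limma camera the call was lost without WT a (median -0.12, adjusted p = 0.114), WT c (median -0.15, adjusted p = 0.0571) or KO c (median -0.02, adjusted p = 0.598). Cell cycle genes, with Ccne2 (-0.30, and -0.13 without KO b) and Tyms (-0.25, and -0.09 without KO a), had a median of -0.08 (adjusted p = 0.0144, and adjusted p = 0.593 with an estimated correlation). In limma camera that call was lost without WT a (median 0.03, adjusted p = 0.86), WT c (median -0.12, adjusted p = 0.0571), KO a (median -0.009, adjusted p = 0.701) or KO b (median -0.09, adjusted p = 0.177). The medians went further down as well, to -0.18 for limb genes without KO b and to -0.17 for cell cycle genes without WT b. Cardiac muscle genes did not pass (median -0.08, limma camera adjusted p = 0.0819, and adjusted p = 0.521 with an estimated correlation) but did without WT b (median -0.13, adjusted p = 0.00295) or KO c (median -0.20, adjusted p = 0.000249), and their members Tnni3 and Csrp3 differed by -0.56 (-0.13 without WT c) and -0.47 (-0.22 without KO a). The other lists that did not pass were retinoic acid, globin, cholesterol synthesis, TALE, haematopoietic stem and progenitor, endothelial, optic cup and eye pigment, p53 target, skeletal muscle and cartilage genes, with medians from -0.13 to 0.24. Among their members, Aldh1a1 differed by -0.94 (-0.54 without WT b) and Cyp26b1 by -0.37 (-0.75 without KO b, -0.19 without KO c). Fdps differed by 0.26 and Fdft1 by 0.21. The p53 targets Eda2r and Trp53inp1 differed by 0.82 (-0.36 without KO a) and -0.26 (-0.09 without WT b), Myh3 of skeletal muscle by 0.32 (-0.05 without KO b) and Col2a1 of cartilage by 0.20 (-0.01 without KO b). Acta1 and Sox6 of the same 2 lists differed by 0.21 (0.12 without KO b) and 0.27 (0.15 without KO a), and Pax6, which patterns eye and neural tube, by 0.26 (0.08 without WT b).

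**Figure D2:**
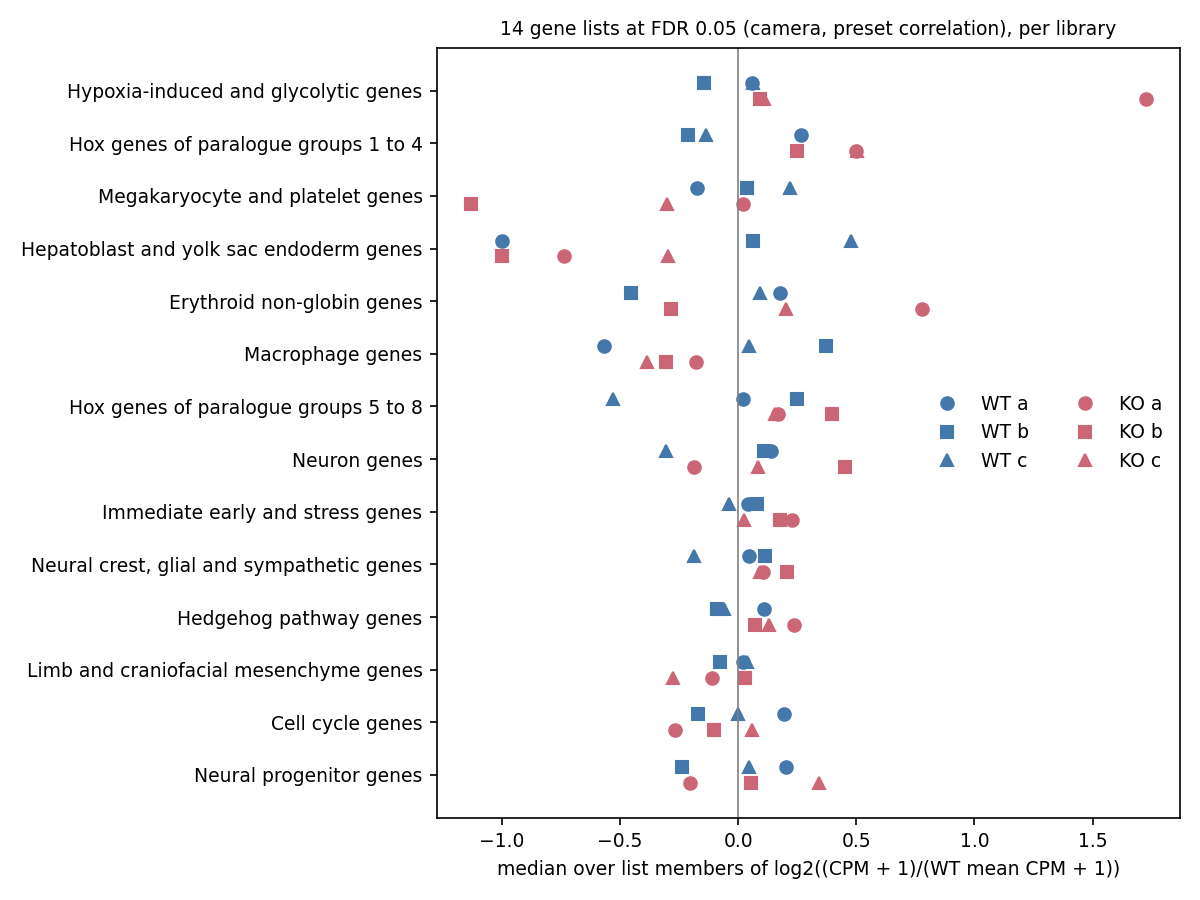
Median over the members of each of the 14 lists of the log2 ratio to the WT mean, per WT (blue) and KO (red) library. The hypoxia list is at 1.73 in KO a and at 0.09 and 0.11 in KO b and c, and the WT libraries spread from -0.998 to 0.477 in the hepatoblast list.

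The authors' deposited table calls 49 genes at an adjusted p under 0.05, 41 higher and 8 lower in KO. These genes were chosen here after their values were seen. In the authors' deposited table, Hspa1a has means of 2.59 in WT and 124 in KO, Bnip3 has 123 and 442, and Vegfa has 308 and 831. Worked back to libraries, Hspa1a, a heat shock gene whose reads can be shared with Hspa1b, was at 367 normalised counts in KO a and at 2 and 2.92 in KO b and c. Bnip3 was at 1032 in KO a and at 145 and 148 in the other KO libraries. Of the 41 genes called higher in the authors' deposited table, 38 were highest in KO a, and 39 were at least 2-fold above the WT mean in KO a, against 4 in KO b and 2 in KO c. Over those that edgeR could test, the median log2 difference was 1.20 with all libraries (35 genes) and 0.28 without KO a (36 genes). The 8 called lower in the authors' deposited table are Ppbp, Pf4, Alb, Apoa1, Krt15, Cryaa, mt-Tl1 and Gm1821. Gm1821 was at 402 normalised counts in WT b and at most 7.87 in every other library, and Cryaa, a lens crystallin gene, was at 66.1 in WT b, 14 in KO b and at most 4.52 elsewhere. With edgeR, 41 of these 49 genes could be tested. All 41 kept the direction given in the authors' deposited table, and 31 had an unadjusted p under 0.05. The tested counts were worked back from the same group means, and the genes were called on the same libraries. The direction was therefore nearly fixed in advance, and neither number is an independent check.

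The second comparison asks which transcripts differ in 1 Prep1 hypomorph library against 1 littermate WT library, so none of its differences has a replicate check and no p-value is given. The WT library holds 23 counts of the female transcript Xist together with 181 of Ddx3y and 118 of Uty from the Y chromosome, against 1, 295 and 215 in the hypomorph, and whether it holds 1 embryo stays open. Pknox1, the targeted gene, had 129 counts in WT and 14 in the hypomorph, a log2 ratio of -3.58. Liver and yolk sac transcripts, led by Alb, were higher in the hypomorph, as were platelet, red cell, macrophage, muscle and some cartilage transcripts. Lin28a, Igdcc3 and Hmga1, which are high in early embryonic cells, were lower, together with heart muscle and cell cycle transcripts. Ratios are of TMM-scaled counts with a prior count of 2, and bracketed ranges are 95% exact intervals that cover counting error only.

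Pknox1 (chromosome 17, 31701718 to 31744638 in mm9) had a log2 ratio of -3.58 (-4.70 to -2.99), the direction that the label calls for. The other TALE genes reported here moved less, with Irx3 at -0.65 (-0.91 to -0.39), Irx5 at -0.37, Meis3 at -0.35 (-0.60 to -0.11), Meis1 at -0.27 (-0.44 to -0.11) and Pbx2 at -0.27 (-0.40 to -0.13). Meis2 at -0.05, Pbx3 at 0.01 and Pbx4 at 0.32 (19 and 36 counts) were within counting error of 0. The lowest ratio among genes with at least 50 counts was that of Slc15a2, a peptide transporter gene, with 82 counts in WT and 2 in the hypomorph (log2 -4.83, -9.01 to -4.04). Lin28a, a regulator of let-7 microRNA processing, was at -1.89 (163 and 64 counts), Igdcc3 at -1.56 (1131 and 573) and Hmga1, a chromatin protein gene, at -1.20 (712 and 462). Gm23935, Card14, Adamts4, Atp6v0c, Pop5, Gramd3 and Lars2 completed the lowest 12, between -1.69 and -1.20.

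The highest ratio among genes with at least 50 counts was that of Alb, with 59 counts in WT and 598 in the hypomorph (log2 2.73, 2.37 to 3.17). Krt14, a keratin of the basal epidermis, was at 2.61 (6 and 67 counts), Cav1, a caveolae gene, at 2.09 (59 and 385) and Nfix, a transcription factor gene, at 2.02 (21 and 135). Ppbp was at 2.21 (7 and 57 counts), the opposite side of its value in the Meis1 comparison. Hbb-b1, an adult beta globin gene whose reads can be shared with Hbb-b2, was at 2.21 (9 and 71 counts). Penk, March1, Htra1, C1qtnf7, Klf4 and Hsd3b6 completed the highest 12, between 2.08 and 1.81.

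Hepatoblast and yolk sac endoderm genes had a median log2 ratio of 1.15 over 19 measured members, the 100th percentile of 10000 random lists of the same size matched on mean expression. Apob was at 1.52, Rbp4 at 1.51 and Trf, the transferrin gene, at 1.47. The random lists hold unrelated genes, so no percentile given here allows for members that vary together. The Meis1 WT libraries also spread in such lists. Against the WT mean, hepatoblast medians were -0.998, 0.064 and 0.477 in WT a, b and c. Skeletal muscle medians were -0.371, 0.313 and 0.021, and platelet medians, which spread less, were -0.174, 0.037 and 0.219. Megakaryocyte and platelet genes had a median of 0.68 (percentile 100), with Clec1b at 1.47 and P2rx1 at 1.42, and macrophage genes 0.59 (percentile 99.9), with Mrc1 at 1.22. Globins had a median of 0.59 (percentile 100), with Hbb-b2 at 1.30, Hba-a1 at 0.62 and Hbb-y at 0.59. Erythroid genes other than globins had a median of 0.48 (percentile 100), with Trim10 at 1.42 and Rhag at 0.97. Skeletal muscle genes had a median of 0.56 (percentile 100), with Neb at 1.32 and Myod1, the muscle determination gene, at 1.06. Cartilage genes had a median of 0.32 (percentile 99.9), with Matn4 at 2.59 (3 and 39 counts), Acan at 1.81 (4 and 27) and Col9a3 at 1.74 (30 and 156). The cartilage genes with the most counts moved little, with Col2a1 at 0.09 (2057 and 3282 counts) and Sox9 at 0.03 (859 and 1310), and Hapln1 fell (-0.84, -1.11 to -0.59). Neural crest genes (0.23, percentile 98.4), hypoxia genes (0.17, percentile 99.97) and neuron genes (0.17, percentile 99.98) were also above the central 95% of random lists, with Foxd3 at 1.19, Ndrg1 at 0.76 and Prph at 1.45. Single members of other raised lists also fell beyond counting error, with Des of skeletal muscle at -0.44, Urod of the erythroid list at -0.32, Slc2a1 and Eno1 of the hypoxia list at -0.21 and -0.14 and Nefm of the neuron list at -0.17.

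Cardiac muscle genes had a median of -0.28, below all random lists (percentile 0), with Myh6 at -1.15, Mybpc3 at -0.82 and Myh7 at -0.72. All 29 measured cell cycle genes were below 0 with a median of -0.23 (percentile 0), led by Ccne1 at -0.45 and Aurka at -0.44. In Meis1 WT a, b and c, cell cycle medians against the WT mean were 0.194, -0.172 and 0. Those of cardiac genes, which spread less, were -0.005, -0.078 and 0.092. Cholesterol synthesis genes had a median of -0.23 (percentile 0.04), led by Dhcr7 at -0.62, and neural progenitor genes -0.22 (percentile 0.07), with Nkx6-2 at -0.96 and Sox3 at -0.59. Nppa and Hand2 of the cardiac list (0.52 and 0.44) and Ptprz1 and Fabp7 of the neural progenitor list (0.54 and 0.45) rose beyond counting error. The other 12 lists lay within the central 95%, among them Hox groups 1 to 4 (median -0.08, percentile 14.4), groups 5 to 8 (-0.07, 22.8) and groups 9 to 13 (0.18, 92.6), although Hoxd13, expressed in distal limbs, was at 1.11. TALE (-0.05, percentile 31.4), Hedgehog (-0.09, 18.1), retinoic acid (-0.06, 16.5), limb (-0.05, 19.9), p53 target (-0.03, 35.7), immediate early (0.04, 70.6), optic cup (0.06, 59.6), endothelial (0.08, 86.3) and haematopoietic progenitor genes (0.12, 86.3) made up the rest. Single members of these lists stood apart, with Fgf8 at -1.78, Rxrg at 1.46 and Ikzf1 at 1.25. Lens and trophoblast lists had 1 and 0 measured members and were not tested in either comparison.

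Of 13780 genes with at least 20 counts in the higher Prep1 library, 341 (2.47%) differed at least 2-fold, 277 higher and 64 lower in the hypomorph. The same rule between pairs of the 6 Meis1 libraries gave 167 (WT a against KO c) to 1111 genes, and 414 to 890 between WT libraries, all 3 of which lie above the Prep1 number. The deposited ratio is not scaled for library size, and by it 1747 of the same genes differed at least 2-fold.

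**Figure D3:**
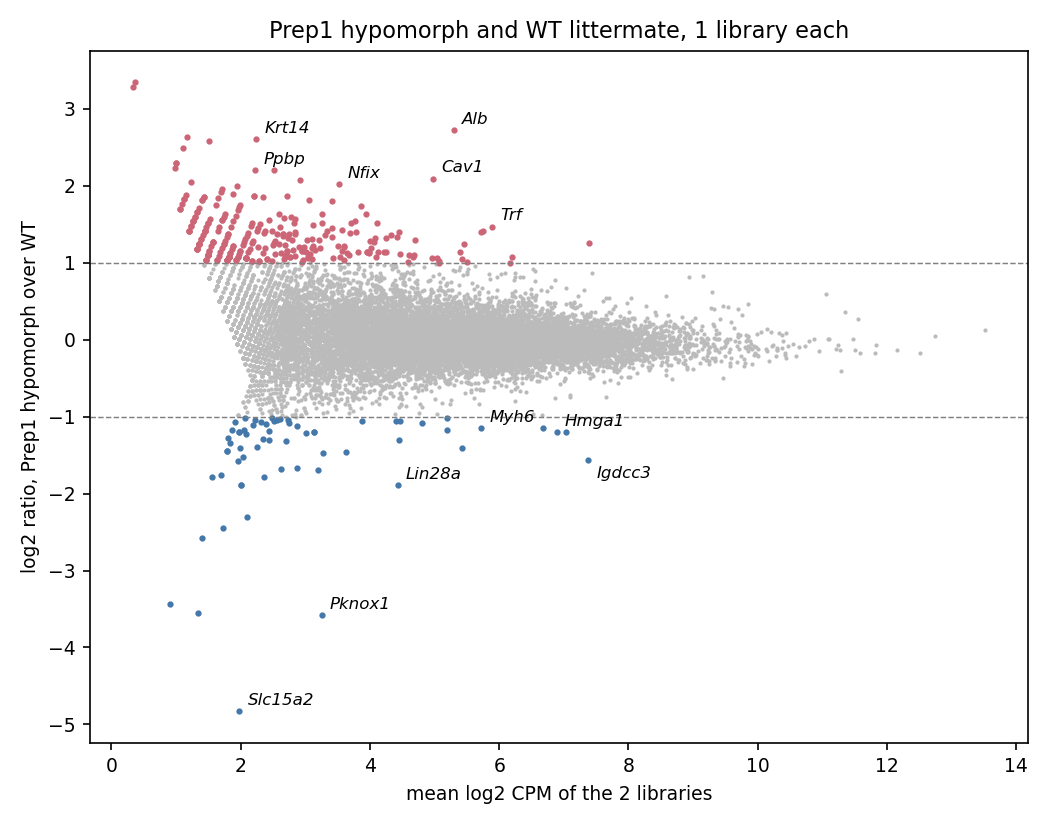
Log2 ratio of the Prep1 hypomorph to its WT littermate against mean log2 CPM, 1 library each, for 13780 genes. Red and blue points are at least 2-fold higher (277) and lower (64), and Pknox1 is at -3.58.

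**Figure D4:**
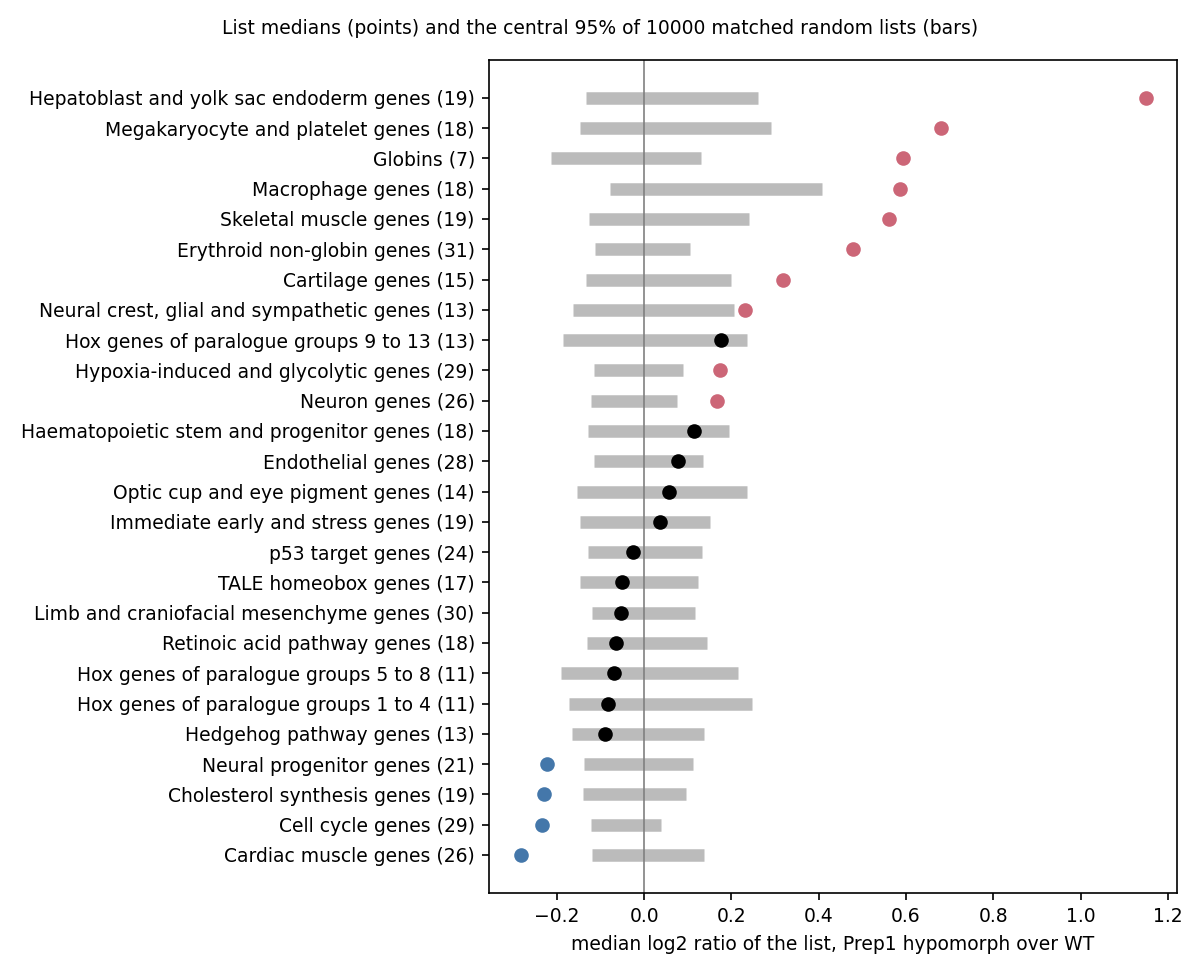
Median log2 ratio of each list (points, number of measured members in brackets) with the central 95% of matched random lists (bars). Hepatoblast genes have the highest median (1.15) and cardiac muscle genes the lowest (-0.28).

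Set side by side, the 2 comparisons share no libraries and showed little common direction. Across 13562 genes, which are not independent replicates, the log2 values had a Pearson correlation of -0.0084 and a Spearman correlation of 0.0583, and leaving out 1 Meis1 library moved the latter between -0.0858 (without WT a) and 0.203 (without WT b). With 0 genes at FDR 0.05 in edgeR for the Meis1 comparison, 0 genes passed both thresholds. Of the genes called in the authors' deposited table, 7 with at least 20 counts in the higher Prep1 library also differed at least 2-fold in the Prep1 pair. Alb, Ppbp, Apoa1 and Krt15 are lower in KO in the authors' deposited table and were higher in the hypomorph, at 2.73, 2.21, 1.40 and 1.13. Gm23935 is higher in KO in the authors' deposited table and was at -1.69, while Ndufa4l2 and Bhlhe40 are higher there and were at 1.70 and 1.37. The 33 measured genes among those called higher in the authors' deposited table had a median Prep1 log2 ratio of 0.29 (percentile 100 of matched random lists). The 6 among those called lower in the authors' deposited table had a median of 1.26 (percentile 100), and the difference in direction between the comparisons was not tested. The random lists hold unrelated genes, so neither percentile allows for members that vary together. Across 13562 genes the Prep1 ratios had a Spearman correlation of 0.28 with the log2 ratio of Meis1 WT b to WT a. For WT c to WT a and WT c to WT b it was 0.222 and -0.162.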

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

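Of the tests in this part, only the thinning of the deeper Prep1 library, added after the data were seen, was chosen before its own result was seen. In 3 named genes the comparisons lie on opposite sides by at least 2-fold, the Meis1 groups do not overlap, and the higher Prep1 library has at least 20 counts, with the 2-fold limit chosen after the values were seen. Ppbp had a log2 value of 2.21 in the Prep1 hypomorph and -5.11 in the Meis1 KO, Pcdhb18 1.54 and -1.78, and Gm23935 -1.69 and 1.27, and the difference was not tested. Also on opposite sides by at least 2-fold are Rgs18 (1.42 and -2.34, with 16 counts in the higher Prep1 library), and Alb, Apoa1, Apob and Krt15, whose Meis1 groups overlap. With 10 splits of the 6 Meis1 libraries into 3 and 3, a share under 0.05 cannot be reached. The real split gave 0 genes at FDR 0.05 with edgeR (225 at an unadjusted p under 0.05, 1 gene with DESeq2 and 0 with limma-voom) and the highest of the others 0, and since every one of the 10 splits gives at least 0, this count says nothing about chance. The real split gave 14 lists, the highest other 13, so 1 of the 10 splits, the real one, gave as many. The split of WT a, KO a and KO c from the rest gave 1772 genes at an unadjusted p under 0.05, which points to a structure of the libraries that does not follow genotype.

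The genes called higher in KO in the authors' deposited table had a median log2 ratio to the WT mean of 2.16 in KO a, 0.13 in KO b and 0.26 in KO c. A rise of the same size in all 3 KO libraries is argued against by the median log2 difference of their tested genes, 0.28 without KO a against 1.20 with it. A smaller shared rise stays open: without KO a, 31 of 36 of these genes, picked for being higher against the same WT libraries, were higher in KO, and the hypoxia list had a median of 0.10 (limma camera adjusted p = 0.00388, and with all libraries adjusted p = 0.417 with an estimated correlation). Also open and not tested is what set KO a apart, which could be low oxygen or handling before RNA was taken, a harsher course of the genotype, or a library effect. The 14 called genes that belong to the hypoxia list, among them Adm, Bnip3, Slc2a1 and Vegfa, do not tell these apart.

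The platelet list had a median log2 difference of -0.46 in the Meis1 KO. A lower share of all blood cells alike in the KO group is argued against by the erythroid list. It was at 0.29 with all libraries and at -0.015 without KO a, where the platelet median was -0.83. For KO b alone a lower share stays open, since both lists lay below the WT mean, erythroid at -0.285 and platelet at -1.13. Erythroid medians were 0.778 in KO a, 0.204 in KO c and -0.454 in WT b. That 1 library carries the platelet fall cannot be told apart from a fall in all KO libraries. The platelet median came to -0.17 without KO b, and KO a stood at 0.02. A fall that takes in other tissue stays open, since the macrophage list was at -0.39, the hepatoblast list at -0.74 and Lmo2 at -0.52. Per library, though, the macrophage median was lowest in WT a (-0.57), and the hepatoblast median of WT a (-0.998) was level with KO b. An effect of the genotype also stays open and was not tested.

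In the Prep1 hypomorph, 81.2% of the genes past 2-fold were higher. With the deeper library thinned to the depth of the other, 72.4% of 301 genes were higher (exact 95% interval 67.0 to 77.4), which argues against depth as the whole cause. That interval treats the genes of a single library pair as independent, so it covers no spread between embryos and can be too narrow. Differences that also part WT libraries stay open, since the Prep1 ratios of these genes had a Spearman correlation of 0.307 with the log2 ratio of Meis1 WT b to WT a (0.259 and -0.179 for the other pairs of WT libraries). An effect of the Prep1 allele is not separable from a difference between 2 single libraries.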

How the results depend on the processing

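The robust fit, surrogate variables, authors' values, thinning, and the list and named-gene runs under these and other scalings were chosen after seeing the data, thinning alone with its prediction written before its own result was seen. For Meis1 genes at FDR 0.05, DESeq2 gave 1, 2 surrogate variables gave 2, and 49 were called in the authors' deposited table, against 0 with edgeR (225 at an unadjusted p under 0.05), and each fit without 1 library gave 0. The genes shared with the authors' calls were 1 with DESeq2 and 2 with 2 surrogate variables. Of the lists, 0 passed with an estimated correlation and 0 with fry, against 14, and 7 to 15 passed without 1 library. The cause was not tested. Without 1 library the camera adjusted p of neuron genes ran from 5.1e-09 to 0.798 and that of cell cycle genes from 7.13e-07 to 0.86, with the direction reversed at the upper end. For lists, 74 results kept direction and side of the threshold, 30 were weaker and 1 stronger across settings, and without 1 library these were 66, 20 and 2.

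For named Meis1 genes, 775 of the results across settings and 463 of those without 1 library kept their direction and side. Pbx2 turned to 0.005 with DESeq2's size factors, 0.003 without globins, 0.005 with DESeq2, and 0.009 and 0.033 with 1 and 2 surrogate variables. Mkx turned to 0.005, 0.003 and 0.005 under the first 3 of these. With 2 surrogate variables Irx5 was at -0.051 and Eda2r at -0.187. Without 1 library the ranges that crossed 0 were Meis3 -0.075 to 0.152, Pbx2 -0.048 to 0.042, Pknox2 -0.088 to 0.239, Tgif1 -0.033 to 0.168, Irx2 -0.257 to 0.066, Irx4 -0.31 to 0.225, Irx5 -0.087 to 0.232, Mkx -0.298 to 0.157, Hba-a1 -0.037 to 0.534, Myh3 -0.051 to 0.654, Col2a1 -0.01 to 0.376 and Eda2r -0.363 to 1.276. The cause was not tested.

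The Prep1 count of 341 genes was 146 with at least 50 counts and 595 with at least 10, which test fewer and more genes, and 1747 by the authors' unscaled ratio, where 98.8% were higher against 81.2%, a ratio with neither library scaling nor a prior count. Other settings gave 264 to 399. Across settings 902 results of named genes kept their direction within counting error, and 1, that of Slc15a2 with a prior count of 5, moved toward 0 by more than it. Side by side, the Spearman correlation of 0.0583 was 0.0882 with at least 50 counts and -0.0858 to 0.203 without 1 library. Genes past both thresholds were 7 with the authors' calls against 0, and the cause was not tested.

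No paired analysis was possible because the groups share no replicate numbers and the sample codes cannot be tied to the recovered libraries. For the same reason a covariate for the series of sample codes was not run. Alternatives to a pseudocount and to a low-value filter on normalised values were not run, because counts were recovered. Depth, between 4000984 and 6263123 counts per library, limits what can be said of genes with few counts.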

Other observations

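All tests drawn on in this part were chosen only after the result was seen. Sex-linked transcripts read as follows. In the 6 Meis1 libraries Xist, expressed from the inactive X chromosome of females, had 0 to 2 counts, and Ddx3y of the Y chromosome had 221 to 373 counts. The Prep1 WT library had 23 counts of Xist and 181 of Ddx3y, and the hypomorph 1 and 295.

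Lin28a, Igdcc3 and Hmga1, 3 genes that were low in the Prep1 hypomorph and were chosen after their values were seen, also differed between the Meis1 WT libraries. Lin28a read 41.9, 4.97 and 10.2 CPM in WT a, b and c, Igdcc3 read 241, 27.9 and 46.7 CPM, and Hmga1 read 181, 36.1 and 145 CPM. In the KO libraries a, b and c, Lin28a read 12.1, 8.38 and 27 CPM, Igdcc3 77.1, 62.8 and 167 CPM, and Hmga1 131, 38.5 and 163 CPM. In the Prep1 pair Lin28a read 41.1 CPM in WT and 10.8 CPM in the hypomorph, and Igdcc3 285 and 96.5 CPM. Alb ran the other way in the WT libraries, at 7.53, 86.2 and 78.8 CPM in Meis1 WT a, b and c, and at 14.9 CPM in the Prep1 WT and 101 CPM in the hypomorph. In the KO libraries Alb was at 10.9, 21.8 and 21.7 CPM in a, b and c. From KO a to KO b it rose while the 3 genes fell, but in KO c, where all 3 were highest, it was level with KO b. A difference in developmental progress between embryos of the same nominal day may be a candidate explanation, which the correlation of 0.307 between the Prep1 ratios and the ratio of Meis1 WT b to WT a leaves open and the KO values of Alb do not favour. The stage of the embryos is not given in the sources used here, and this explanation was not tested on its own.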
